A study of Homo sapiens with 4 samples.

How the data were processed

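The study measured total RNA from peripheral blood lymphocytes of 4 healthy, non-diabetic volunteers. Per the labels, RNA was purified with RNeasy mini kits, converted to biotin-labelled single-stranded cDNA and hybridised to Affymetrix Human Gene 1.0 ST arrays. Per the submitters' processing notes, Affymetrix Expression Console (version 1.1.1) turned the scans into expression values. The deposited values are linear intensities, 1 per probe set and array, as their range from 0 to 25079.2 showed. The summarization, background correction and normalization behind them are not given in the sources used here, and the array medians lay close together. Between 129 and 265 probe sets per array were listed at an intensity of 0. For this work the deposited intensities were turned into log2(intensity + 1), so folds are on that scale and understate the change of low genes.

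Each array held 33297 probe sets. A platform annotation, which can be old, listed 21214 of them with a gene and did not list 12083. Of the listed probe sets, 1754 named several genes and were left out, and 19460 named 1 gene. Symbols of 19429 of these were found through their gene number in the RefSeq gene table of the assembly GRCh38.p14, which was used for names only. Sex-linked marker genes were left out of everything. HLA and KIR genes, antigen receptor segments and genes with common copy number differences were kept in counts and never named. A gene was represented by the probe set with the highest mean, which mattered for 768 of the 18391 measured genes.

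A gene was called above background when it exceeded, on all 4 arrays, the 95th percentile of the 361 olfactory receptor genes on the same array. The limits were 7.58, 7.49, 7.62 and 7.65 log2 units in samples 1 to 4, and 8962, 9127, 9097 and 8490 genes exceeded them. A gene above background was called variable when its highest and lowest sample differed by 1 or more log2 unit. Lists of cell type markers, cell states, chromatin genes, metabolism, immune function and organs other than blood (42 lists with 617 symbols, of which 565 were measured) were fixed before the data were examined. Some genes stand in more than 1 list, and many markers are shared between blood cell types.

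The share of members above background was compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 42 lists and a threshold of 0.05. Lists with 5 or more members above background were tested for moving together. The statistic, here called shift SD, was the SD over the 4 arrays of the mean deviation of the members from their own means. It was compared, one-sided, with 10000 random lists of equal size drawn from genes of like mean level in 20 bins, which is called the permutation test, with Benjamini-Hochberg adjustment over 28 lists. The share of variable members was compared with the other genes above background by Fisher's exact test in the same way. Genes are not independent replicates, so these p-values describe the 4 arrays and do not extend to other people. Named genes were the first 2 measured genes of each list (1 for organs other than blood), the 25 variable genes with the largest SD, and variable members of a list. All others, among them MZB1, CD38, SPP1, CXCL9, FCN1 and the GBP genes, were chosen after their values were seen.

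The tests were tried on simulated data made from the 6954 genes above background. Deviations were shuffled between genes and arrays, so simulated genes varied independently, which members of real lists need not do. With no shift, 1 of 40 simulated lists of 13 genes was called, and at a shift SD of 0.3, 20 of 20 were. For the share of variable genes, 0 of 40 lists of 15 genes were called with no enrichment, and 39 of 40 were called when 50% of the members varied. Alternatives fixed before the data were examined were quantile normalization, median centring, the 99th percentile, a limit on the mean, organ lists as the negative set, the mean over probe sets, log2(intensity + 16), no filter, a 1.5-fold range, an SD of 0.5, no matching on level, the median of the members, and leaving out each sample. The value of the plasma cell list with no filter was added after the data were seen, because it had fewer than 5 members above background. Also added then was the setting of values below an array's limit to that limit in 6 differences between samples and in the sample 4 deviations of other blood cell lists. The rules for a smaller share of T cells, macrophage maturation, array scaling, loss of intact RNA and an unfolded protein response were changed after their values had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.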

Results

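Transcript levels were measured in freshly isolated peripheral blood lymphocytes of 4 healthy, non-diabetic volunteers. The cells were untreated, and each volunteer gave 1 RNA sample, hybridised to 1 whole-transcript array. The 4 samples formed 1 group and are called samples 1 to 4. The labels gave no contrast between groups, so the design implied a description of which genes were above background and of how far the 4 samples differed. The expression values were collected to be combined with chromatin immunoprecipitation array data, which were not analysed here. The arrays had median probe set intensities of 147.58, 139.04, 153.1 and 145.01 in samples 1 to 4. Levels below are log2 intensities given as mean ± SD over n = 4 samples. No genome build was named by the values used here, so no coordinates are given. The number of arrays limits the precision, and without technical repeats the spread between samples holds both person and array differences.

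Transcripts of T cells, cytotoxic lymphocytes and monocytes were all above background. Of the genes that mark T cells, 17 of 18 exceeded the limit on every array, among them the T cell receptor signalling subunits CD3E (10.15 ± 0.38) and CD3D (9.11 ± 0.31). The CD8 and naive or memory T cell genes were above the limit in 8 of 8 cases, with the co-receptor chains CD8A at 9.40 ± 0.56 and CD8B at 8.25 ± 0.57. Cytotoxic and natural killer cell genes passed in 18 of 21 cases, including the granule proteins GNLY (10.55 ± 0.46) and NKG7 (11.59 ± 0.36). Monocyte genes passed in 16 of 16 cases, with the lipopolysaccharide co-receptor CD14 at 10.71 ± 0.34 and the lysozyme gene LYZ at 13.10 ± 0.14. Levels in this report are therefore those of each RNA sample as a whole and cannot be assigned to lymphocytes alone. Each of these lists held more genes above background than the 38.5% seen among other genes, with adjusted p of 2.15e-05 (T cell), 0.00169 (CD8), 8.24e-05 (cytotoxic) and 9.76e-06 (monocyte) by Fisher's exact test. Lymphocyte transcription factors followed with 18 of 20 genes (adjusted p = 2.77e-05, Fisher's exact test), among them IKZF1 at 10.39 ± 0.23 and RUNX3 at 9.92 ± 0.30.

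Among the lists of other blood cells, only neutrophil genes passed the test for being seen less often. Among neutrophil genes, 1 of 16 was above background, fewer than among other genes (adjusted p = 0.0223, Fisher's exact test), and the chemokine receptors CXCR1 and CXCR2 lay below the limit at 6.27 ± 0.74 and 6.67 ± 0.61. That call was lost without sample 1 (adjusted p = 0.0747, Fisher's exact test), at the 99th percentile (0.264) and with the organ lists as the negative set (0.528). Basophil, mast cell and eosinophil genes gave 0 of 7 (adjusted p = 0.0970, Fisher's exact test), and the B cell list 2 of 17 (adjusted p = 0.0506, Fisher's exact test), neither past the threshold. Both crossed it under alternatives: the B cell list with the mean over probe sets (0.0483) and without sample 2 (0.0488), and the basophil list with a limit on the mean (0.0182), as adjusted p of Fisher's exact test. The B cell surface gene MS4A1, which encodes CD20, was above the limit at 9.18 ± 1.01, whereas CD79A, a subunit of the B cell receptor, was not (7.42 ± 0.69). The counts were 3 of 8 for plasma cell, 2 of 9 for dendritic cell, 2 of 14 for platelet and 3 of 10 for erythroid genes, and none of these lists passed the test. Even so, the beta-globin gene HBB reached 11.21 ± 0.94 and the platelet chemokines PPBP and PF4 reached 8.44 ± 0.67 and 8.75 ± 0.37.

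Genes that write and erase histone marks were widely above background. Of 74 genes in the chromatin lists, 55 exceeded the limit on all arrays and 2 varied by 2-fold or more. Histone demethylases passed in 13 of 14 cases, with KDM1A at 8.51 ± 0.36 and KDM4A at 8.60 ± 0.28. Histone acetyltransferases passed in 9 of 11 cases, with EP300 at 9.17 ± 0.36 and CREBBP at 10.06 ± 0.15. Methyltransferases passed in 14 of 21 cases, with KMT2A at 9.83 ± 0.21 (8.54 with the mean over probe sets) and SUV39H1 below the limit at 6.89 ± 0.47. Deacetylases and sirtuins passed in 12 of 17 cases, with HDAC1 at 9.76 ± 0.18 and HDAC3 at 8.99 ± 0.19. Each of the 4 histone lists held more genes above background than other genes did, with adjusted p of 0.00022 (demethylases), 0.0132 (acetyltransferases), 0.0278 (methyltransferases) and 0.0258 (deacetylases) by Fisher's exact test. With the organ lists as the negative set, a stricter limit, none of the 4 passed, with adjusted p of 0.0984, 0.0508, 0.592 and 0.770 in the same order by Fisher's exact test. At the 99th percentile, methyltransferases (0.240) and deacetylases (0.0937) lost the call. The DNA methylation list gave 7 of 11, which did not pass (adjusted p = 0.193, Fisher's exact test), although the maintenance methyltransferase DNMT1 (9.58 ± 0.26) and the de novo enzyme DNMT3A (8.41 ± 0.56) were above the limit.

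The metabolic and protein-handling lists were nearly complete. Glycolysis genes passed in 14 of 14 cases, ribosomal proteins in 10 of 10, heat shock proteins and chaperones in 13 of 13, antigen presentation in 10 of 10, and both oxidative phosphorylation and the proteasome in 13 of 15. The glucose transporter SLC2A3 stood at 11.57 ± 0.69 and the hexokinase HK1 at 9.09 ± 0.23. RPL3 stood at 12.30 ± 0.23, the ATP synthase subunit ATP5F1B at 11.11 ± 0.14, and the class I light chain B2M at 12.78 ± 0.19. All 6 lists passed Fisher's exact test, with the largest adjusted p at 0.000677. Insulin signalling genes passed in 12 of 17 cases (adjusted p = 0.0258, Fisher's exact test), yet the receptor INSR (6.62 ± 0.56) and its substrate IRS1 (5.96 ± 0.57) were below the limit. Of the genes at loci tied to type 1 diabetes, 12 of 23 were above background (adjusted p = 0.263, Fisher's exact test), with the phosphatase PTPN22 at 8.34 ± 0.63 above it and the checkpoint receptor CTLA4 at 7.90 ± 0.34 not above it on every array. Checkpoint and costimulation genes passed in 11 of 16 cases (adjusted p = 0.0410, Fisher's exact test), with LAG3 at 8.06 ± 0.37 and TIGIT at 8.76 ± 0.35. The insulin and checkpoint calls were lost without sample 4, with adjusted p of 0.0563 and 0.0888 by Fisher's exact test, and with the organ lists as the negative set (0.0563 and 0.770). The checkpoint call was also lost at the 99th percentile (0.471).

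Cell cycle genes and secreted effector cytokines did not pass the test against the 38.5% of other genes above background. The cell cycle list gave 3 of 15 genes (20%, adjusted p = 0.253, Fisher's exact test), with the proliferation markers MKI67 (5.79 ± 0.93) and TOP2A (5.90 ± 1.04) below the limit. Effector cytokines gave 5 of 15 (33.3%, adjusted p = 0.834, Fisher's exact test), which were CCL5, LTB, TGFB1, IL32 and IL16, named after their values were seen, while IFNG (5.79 ± 0.84) and IL4 (4.40 ± 1.02) were below it. The remaining lists that did not pass Fisher's exact test were CD4 helper and regulatory T cells (6 of 11), immediate early genes (10 of 18), inflammatory cytokines (9 of 18), interferon response (8 of 19), hypoxia (5 of 11), Toll-like receptors (7 of 10), chemokine receptors (8 of 16) and the circadian clock (8 of 14). Of these, immediate early genes passed at the 99th percentile (adjusted p = 0.0284, Fisher's exact test), and Toll-like receptors passed with a limit on the mean (0.0413) and without sample 3 (0.0394). In the lists of organs other than blood, 11 of 78 genes were above background. Germline and testis genes gave 0 of 14, fewer than other genes (adjusted p = 0.00485, Fisher's exact test, and 0.117 at the 99th percentile), and the protamine gene PRM1 stood at 6.34 ± 0.37. Liver, brain, muscle, and epithelium and skin gave 2 genes each and pancreas gave 3, without passing the test, although liver (adjusted p = 0.0182, Fisher's exact test) and brain (0.0261) passed with a limit on the mean, as lists with fewer genes above it. The skeletal muscle actin gene ACTA1 was above the limit at 8.98 ± 0.21. CKM of the muscle list (10.51 ± 0.20) and PDX1 of the pancreas list (10.33 ± 0.22), named after their values were seen, lay higher. Organ genes were thus called too, so a level above the limit does not by itself show transcription. In all, 6954 of 18391 measured genes (37.8%) were above background, where 9 of the 361 olfactory receptor genes used as the negative set also passed. Of the 42 lists, 17 held more genes above background than other genes and 2 held fewer.

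**Figure D1:**
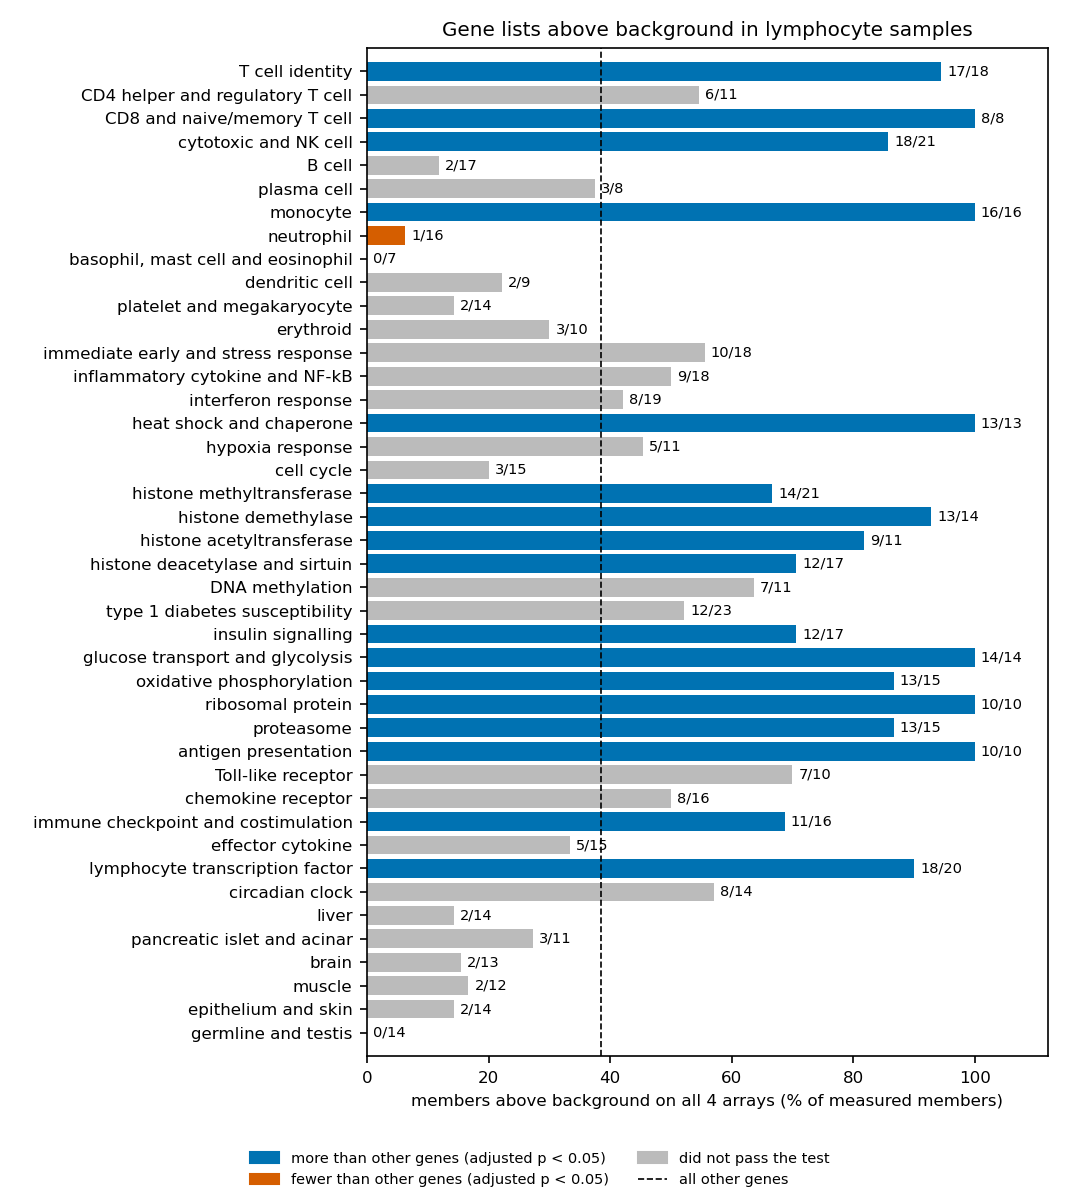
Share of the measured members of each gene list that were above background on all 4 arrays, as percent of members on the horizontal axis, with the counts beside each bar. The dashed line marks all other genes at 38.5%; the 17 lists with more genes above background and the 2 with fewer (adjusted p under 0.05, Fisher's exact test) are coloured, and the remaining lists are grey.

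The arrays resembled each other across genes. Pearson's r across all measured genes averaged 0.906 over the 6 pairs of samples, from 0.882 for samples 2 and 3 to 0.924 for samples 1 and 3. Over genes above background the order differed, from 0.863 for samples 3 and 4 to 0.926 for samples 1 and 2. Genes are not independent replicates, so these values describe the arrays only. No pair of arrays was near-identical, since between 0.129% and 0.186% of the probe sets held the same value in both. A gene above background had a median SD of 0.28 and a median fold range of 1.53 between its lowest and highest sample.

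Between the 4 people, 486 genes above background (6.99%) differed by 2-fold or more, and 20 by 4-fold or more. CXCL10, a chemokine induced by interferon, had the widest range among the 25 variable genes with the largest SD, at 11.1-fold, with levels of 11.74, 9.77, 8.50 and 8.27 in samples 1 to 4. The tryptophan-degrading enzyme IDO1 (4.42-fold), the ion channel gene CALHM6 (5.85-fold), ANKRD22 (7.31-fold) and the monocyte chemoattractant CCL2 (5.09-fold) were likewise highest in sample 1. The glycoprotein gene GPNMB ranged over 7.07-fold and was low in sample 3 at 8.68, against 11.12, 11.35 and 11.51 in samples 1, 2 and 4. Sample 3 was highest for the cystine transporter SLC7A11 (10.24), the growth factor HBEGF (9.91), ITM2C (10.26) and the methionine sulfoxide reductase MSRB3 (11.92). Sample 4 was highest for the proteoglycan VCAN (11.75), the lectin receptor CLEC12A (9.89), NRGN (9.75) and the globins HBB (12.22) and HBD (11.47). It was lowest for the T cell factor LEF1 (9.05), the granzyme GZMK (8.05) and NELL2 (7.82). Sample 2 was lowest for SPAG16 (7.69) and MS4A8 (7.53) and highest for TMEM176A (10.20) and TMEM176B (11.38). Where a variable gene had another probe set above background, that probe set was highest in the same sample for 14 of 16 genes, against 25% by chance. Both probe sets read the same RNA on the same array, so this does not separate person from array differences.

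Of 28 lists tested, 13 moved together between samples by more than random genes of like level. The adjusted p was 0.0004 for the 7 lists with the strongest result in a permutation test against 10000 random lists, whose smallest possible unadjusted p was 0.0001. These lists were interferon response, glycolysis, inflammatory cytokines, CD8 and naive T cells, T cell identity, cytotoxic cells and monocytes. The remaining 6 were hypoxia (0.0285), immediate early genes (0.00336), proteasome (0.00218), ribosomal proteins (0.0021), heat shock (0.0257) and antigen presentation (0.0485), each given as the adjusted p of the same permutation test. The cytotoxic, glycolysis, interferon and inflammatory lists kept their call in every setting that could test them, including without each sample in turn. Heat shock was lost without sample 1 or 4 (adjusted p of 0.0799 and 0.363, permutation test) and with the organ lists as the negative set (0.260), and antigen presentation in 7 of 15 settings.

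T cell genes were lower in sample 4 than in the others. The mean deviation of the 17 T cell genes from their own means was −0.50 in sample 4 and between +0.11 and +0.24 in samples 1, 2 and 3, and 15 of the 17 were lowest in sample 4. Relative to the mean of the other samples, the list was 0.66 ± 0.11 (SE over genes) log2 units lower there, or 1.58-fold. The variable members were the costimulatory receptor CD28, the adaptor LAT, LEF1, BCL11B, UBASH3A and TRAT1, with CD28 at 8.33 and TRAT1 at 9.03 in sample 4. As a list, CD8 and naive T cell genes went the same way, with −0.53 in sample 4 and +0.37 in sample 3, and 7 of 8 were lowest in sample 4. CD8A was the exception, at 9.38 in sample 4 against 9.05, 8.96 and 10.19 in samples 1 to 3. The CD4 helper and regulatory T cell list did not go this way, at +0.10 ± 0.22 (SE over genes) in sample 4, where 4 of the 6 genes were highest. The lymph node homing receptor CCR7 ranged from 11.48 in sample 2 to 9.93 in sample 4. Ribosomal protein genes stood at −0.32 in sample 4, with 10 of 10 lowest there, and proteasome genes at −0.37. Without sample 4 the T cell, CD8, monocyte, ribosomal and proteasome calls were lost, with adjusted p of 0.664, 0.190, 0.198, 0.363 and 0.697 in the permutation test. With the organ lists as the negative set, the T cell call was also lost (adjusted p = 0.164, permutation test).

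Monocyte and cytotoxic genes were higher in sample 4. The 16 monocyte genes lay +0.39 above their own means in sample 4 and −0.27 in sample 2, and 9 of the 16 were highest in sample 4. Against the mean of the other samples they were 0.53 ± 0.13 (SE over genes) log2 units higher, or 1.44-fold. The variable members were CD163, S100A12, VCAN, CSF3R and ITGAM. Cytotoxic and natural killer genes lay at −0.16, −0.32, +0.20 and +0.28 in samples 1 to 4. Of 18 such genes, 11 were highest in sample 4 and 11 were lowest in sample 2. The granzyme gene GZMB ranged from 9.47 in sample 2 to 10.92 in sample 4, and GZMH from 7.60 to 9.32 in the same samples.

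Interferon response genes were higher in sample 1 than in sample 3. The 8 genes deviated by +0.64, +0.24, −0.58 and −0.30 in samples 1 to 4, and 8 of 8 were higher in sample 1 than in sample 3. The difference between these samples was 1.22 ± 0.12 (SE over genes) log2 units, or 2.33-fold. The antiviral GTPase gene MX1 stood at 9.55 in sample 1 and 7.82 in sample 3, IFI44 at 9.28 and 7.70, and IFIT2 at 9.68 and 8.15. Glycolysis genes split the same samples, with +0.44 in sample 1 and −0.53 in sample 3, and 14 of 14 were higher in sample 1. That difference was 0.97 ± 0.12 (SE over genes) log2 units, or 1.96-fold. SLC2A3 stood at 12.36 in sample 1 and 10.69 in sample 3, lactate dehydrogenase LDHA at 11.81 and 10.49, the isomerase GPI at 10.76 and 9.22, and the phosphofructokinase PFKP at 9.50 and 8.05. The 5 hypoxia genes above background lay at +0.37 in sample 1 and −0.35 in sample 3, a call lost without sample 1 (adjusted p = 0.165, permutation test) or sample 3 (0.0957).

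Inflammatory genes were highest in sample 1 and lowest in sample 4, and immediate early genes were highest in sample 3. The inflammatory list deviated by +0.45 in sample 1 and −0.48 in sample 4, with 7 of 9 genes lowest in sample 4. The pro-inflammatory cytokine IL1B stood at 11.12 in sample 1 and 11.13 in sample 3, against 9.75 in sample 2 and 9.77 in sample 4. Immediate early genes lay at +0.39 in sample 3 and −0.23 in sample 1, and 8 of 10 were highest in sample 3. Among them, FOS ranged from 7.81 in sample 1 to 9.82 in sample 3 and EGR1 from 8.67 to 10.41 in the same samples. That call was lost without sample 3 (adjusted p = 0.319, permutation test) and with the organ lists as the negative set (0.265).

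The histone lists did not pass the test for moving together between samples, which could miss small shifts. The shift SD was 0.06 for methyltransferases, 0.06 for demethylases, 0.11 for acetyltransferases and 0.08 for deacetylases, with adjusted p from 0.458 to 0.748 in the permutation test. The same held for DNA methylation (0.418), insulin signalling (0.748), type 1 diabetes genes (0.259) and oxidative phosphorylation (0.0860), each the adjusted p of the permutation test. Of these, type 1 diabetes genes passed in 2 of 14 settings, with a limit on the mean (adjusted p = 0.0444, permutation test) and with no filter (0.0457), and oxidative phosphorylation in 1 of 15, with the mean over probe sets (0.0432). The lists of CD4 helper cells, Toll-like receptors, chemokine receptors, checkpoint genes, effector cytokines, lymphocyte transcription factors and the circadian clock also did not pass, with adjusted p from 0.203 to 0.703 in the permutation test. Simulated lists of 13 genes that otherwise varied independently were called in 4 of 20 cases at a shift SD of 0.1 and in 19 of 20 at 0.2.

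Variable genes were more frequent than among other genes in 12 lists, of which 9 also moved together. The share was 6 of 8 for interferon response (adjusted p = 3.93e-05), 9 of 18 for cytotoxic cells (2.85e-05) and 7 of 14 for glycolysis (0.000162), by Fisher's exact test. It was 6 of 17 for T cell identity (adjusted p = 0.00503) and 4 of 8 for CD8 and naive T cells (0.00736), by Fisher's exact test. The remaining lists were monocyte (5 of 16), immediate early (4 of 10), inflammatory (3 of 9), hypoxia (3 of 5), CD4 helper (3 of 6), chemokine receptor (3 of 8) and checkpoint (4 of 11), with adjusted p from 0.0131 to 0.0484 in Fisher's exact test. The chemokine receptor list shares CCR7, CCR4 and CX3CR1 with other lists. Likewise, the checkpoint list shares CD28, ICOS and CD27, all among its 4 variable genes, with the T cell lists. Without sample 4, 3 of the 12 lists kept this call. Interferon response lost it without sample 1 (adjusted p = 0.172, Fisher's exact test), cytotoxic cells without sample 2 (0.0950) or sample 4 (0.413), and glycolysis without sample 3, where no gene varied. Quantile normalization and median centring each ended it for the CD4 helper (0.149 and 0.144), inflammatory (0.0627 and 0.0597) and chemokine receptor lists (0.233 and 0.690), as adjusted p of Fisher's exact test. With no filter, only interferon response and hypoxia of the 12 lists kept it, and it was lost for T cell identity (0.679), cytotoxic cells (0.259), glycolysis (0.259) and the others, by the same test. Type 1 diabetes genes gained the call with a limit on the mean (0.00817), and with no filter the demethylase (0.0386) and oxidative phosphorylation lists (0.0299) held fewer variable genes than others, by the same test.

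**Figure D2:**
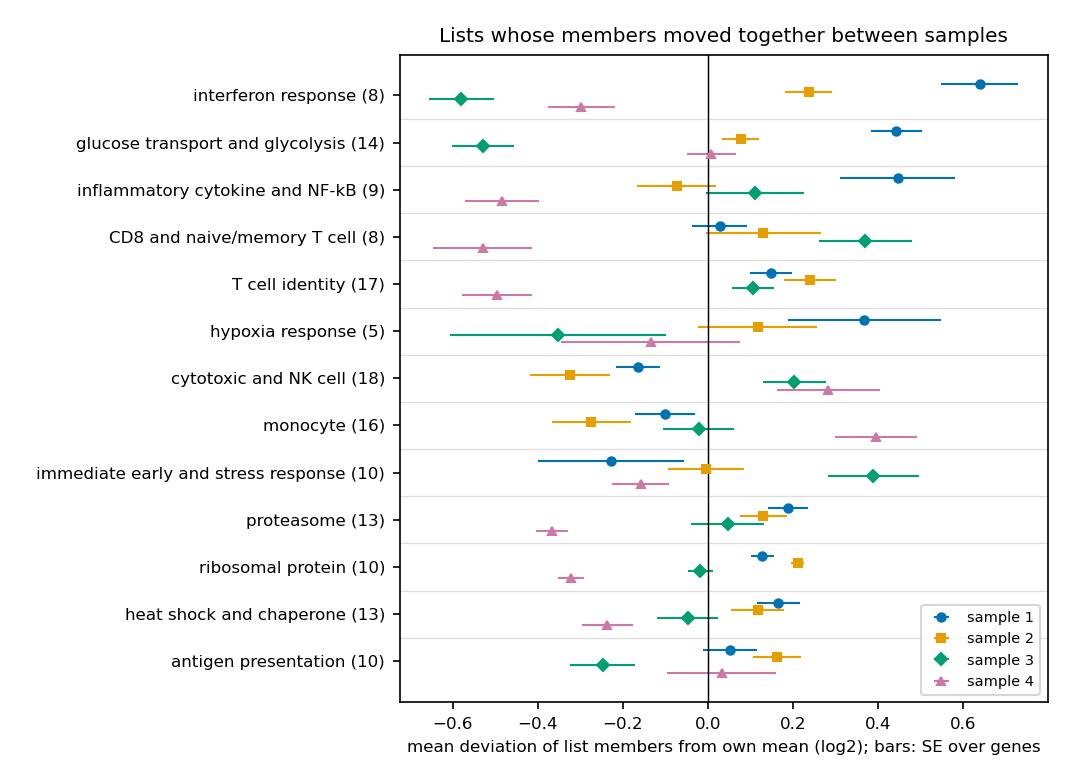
Mean deviation of list members from their own mean over the 4 samples (log2, horizontal axis) for the 13 lists that passed the permutation test, with the number of genes in brackets and bars for the SE over genes. Sample 1 was highest for interferon response (+0.64) and glycolysis (+0.44), and sample 4 was lowest for T cell identity (−0.50) and highest for monocyte genes (+0.39).

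**Figure D3:**
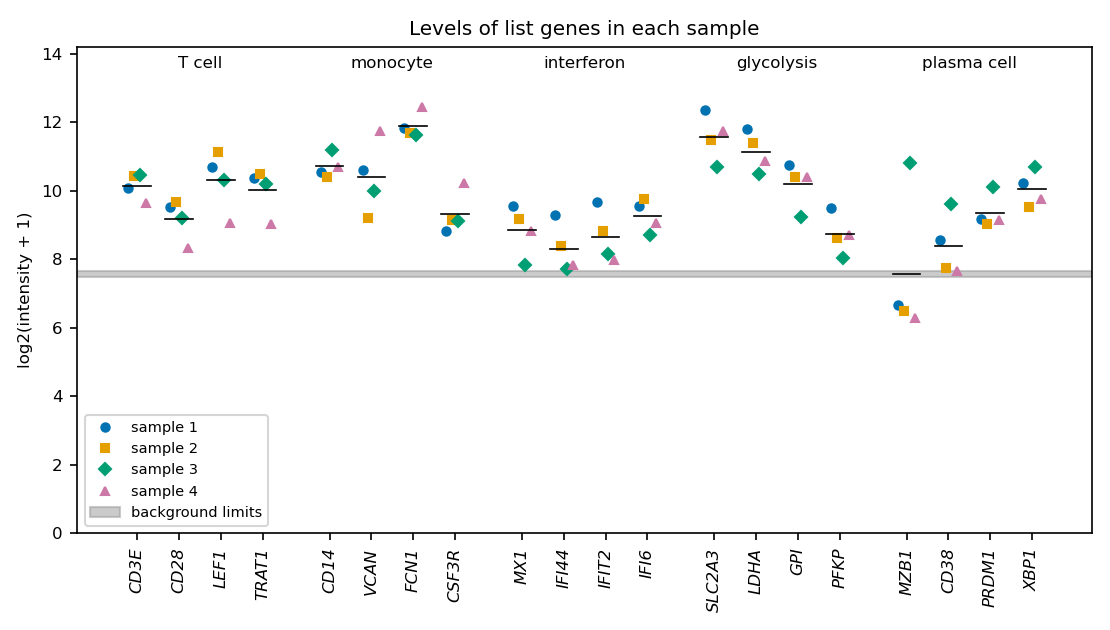
Levels as log2(intensity + 1) of genes from 5 lists, chosen after their values were seen, with a point per sample, a line at the mean and a grey band for the background limits of the arrays. LEF1 was lowest in sample 4 (9.05), SLC2A3 lowest in sample 3 (10.69), and MZB1 was above the band in sample 3 (10.82) and below it in the other samples.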

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

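The tests of explanations given here were all chosen after the results were seen. Their standard errors are over genes on the same arrays, so they hold no spread between people or between arrays. Statements for or against an explanation therefore cover these arrays only. Setting values below an array's limit to that limit was also chosen after the differences as measured had been seen.

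In 12 of 130 tested sets of 4 values, 1 sample stood far from the others by Dixon's ratio (its gap to the nearest value over the whole range), where chance gives about 1 in 20. Of these, 7 were among the 25 genes chosen for the largest SD, a choice that favours a single distant sample, and 5 were among the other 105 sets, about the number that chance gives. Sample 4 stood apart for B2M (ratio 0.850, level 12.50 against a mean of 12.87), CD3D (0.882, 8.65 against 9.27) and NELL2 (0.911, 7.82 against 9.57). Sample 3 stood apart for GPNMB (0.862, 8.68 against 11.32), HBEGF (0.834, 9.91 against 7.92), ITM2C (0.926, 10.26 against 8.33), MSRB3 (0.901, 11.92 against 10.13) and TLR4 (0.839, with a level of 8.68). Sample 2 stood apart for GFAP (0.888, 6.49 against 7.46, below background), MS4A8 (0.919, 7.53 against 9.31) and SPAG16 (0.957, 7.69 against 9.76). Sample 1 stood apart for CCR4 (0.843, 10.39 against 9.48). Outside the genes analysed here, 3018 probe sets with no gene listed in the annotation used here were above the background limit on all 4 arrays.

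T cell genes were lower and monocyte genes higher in sample 4. One scaling factor per array as the whole cause is argued against, since the 48 genes of the 4 histone lists lay 0.484 ± 0.0882 (SE over genes) above the T cell list there and 0.406 ± 0.102 below the monocyte list. The opposite directions of the T cell and monocyte lists already went against it, so the histone lists added little. A general loss of intact RNA stays open, since ribosomal protein genes were lower there (−0.321 ± 0.0301), as were proteasome genes (−0.37 ± 0.04), and higher monocyte genes do not exclude it because values are relative within an array. A smaller share of T cells could account for it but was not decided. Monocyte genes were higher by as much as natural killer genes picked after the pattern was seen (difference of −0.0416 ± 0.160). CD4 helper and regulatory T cell genes were split (+0.10 ± 0.22), with 4 of 6 highest in sample 4 and CCR4 and ICOS lowest. Markers can be shared between blood cell types, so this list does not decide the question. As measured, dendritic, neutrophil, erythroid and platelet genes lay within 2 standard errors of monocyte genes, and B cell (−0.49 ± 0.11), plasma cell (−0.78 ± 0.43) and basophil genes (−0.14 ± 0.22) lay apart, but most genes of all 7 lists were at or below the limit on some array, and set to the limit the neutrophil value fell to +0.10 ± 0.07, apart from monocyte genes, and the B cell value was −0.07 ± 0.04.

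Interferon and glycolysis genes were higher in sample 1 than in sample 3. For these arrays, a larger share of monocytes in sample 1 is argued against, since monocyte genes differed by −0.0783 ± 0.123 (SE over genes). Glycolysis genes differed by 0.97 ± 0.12. Immediate early genes were lower in sample 1 by −0.617 ± 0.272, which argues against an immediate early response under way there. Of these 10 genes, 2 were higher in sample 1, among them CD69 (10.27 against 9.31). Earlier activation during isolation is not excluded, since each person gave 1 sample at 1 time. The inflammatory list lay at +0.45 in sample 1 and +0.11 in sample 3. A response to low oxygen could account for the glycolysis part alone, since the hypoxia list was higher in sample 1 by 0.658 ± 0.192, or 1.35 ± 0.264 with values below the limit as measured. The labels give no handling times or cell counts, and the design names no biological difference between the samples.

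Plasma cell genes were higher in sample 3, by 0.98 ± 0.38 log2 units (SE over 8 genes), or 1.76 ± 0.60 as measured. An unfolded protein response alone may or may not account for it, since the 5 plasma cell genes outside the secretory pathway differed by 0.611 ± 0.333, which was within 2 standard errors of 0, as was the difference as measured. Without SDC1, which was not higher there, CD38, PRDM1, IRF4 and TNFRSF17 differed by 0.825 ± 0.329, but this set was picked after the pattern was seen. A larger share of B lineage cells may or may not account for it and cannot be told apart, since the B cell list differed by −0.150 ± 0.0991 and 15 of its 17 genes were at or below the limit on some array. As measured, before values were set to the limit, that difference was −0.49 ± 0.23. Taken alone, it would have spoken only against more cells that express the B cell list. It does not speak against more plasma cells, which have a list of their own.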

How the results depend on the processing

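Alternatives were fixed before the data were examined, except those said to be added. The count of genes above background was 4093 with the 99th percentile and 1830 with organ lists as the negative set, and lists with more genes above background numbered 11 with organ lists. Variable genes numbered 226 (99th percentile), 1056 (limit on the mean), 83 (organ lists), 5903 (no filter), 3949 (1.5-fold range) and 276 (SD of 0.5), and 250 to 392 when each sample was left out. Lists moving together numbered 6 with organ lists and 7 to 12 when each sample was left out, the lowest without sample 4. Lists with more variable genes numbered 7 (99th percentile), 2 (organ lists) and 6 (no filter, only 2 of them among the 12), and 3 to 9 when each sample was left out, the lowest without sample 4. Mean r across genes was 0.890 over genes above background. The 99th percentile and organ lists left fewer genes to call. A 1.5-fold range and no filter can only add variable genes, and both kept all 486. Leaving out a sample cannot widen the range of a gene, though more genes can then pass the limit. For the rest the cause was not tested. The share of variable genes changed sides for T cell identity (0% with organ lists, 0% without sample 4), immediate early genes (0% with organ lists), glycolysis (0% without sample 3), checkpoint genes (0% without sample 4) and monocyte genes (31.25% with no filter). Leaving out each sample gave ranges of 0% to 35.3% for T cell identity, 0% to 50% for glycolysis and 0% to 36.4% for checkpoint genes. Quantile normalization and median centring changed no call of lists moving together and cannot change genes above background by construction, but each ended 3 of the 12 calls of lists with more variable genes. Of the named genes, 1 mean (KMT2A, 8.54 with the mean over probe sets) moved by more than 1 SD. Added after the data were seen, the plasma cell list had a shift SD of 0.92 with no filter, and it stayed past the threshold with log2(intensity + 16). Values below the limit as measured moved the B cell difference past 2 standard errors and left the other 5 differences on the same side. No paired analysis was possible because there is only 1 group. Of the 17 B cell genes, 15 were at or below the limit on some array.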

Other observations

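The tests and gene lists of this part were chosen after the variable genes were seen, except those with no filter on fixed lists other than the plasma cell list.

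Lists that could not be tested above background also differed between samples when all genes were used. The plasma cell list had a shift SD of 0.92, with +1.32 in sample 3 (adjusted p = 0.000525, permutation test). MZB1, a gene of antibody-secreting cells chosen after its values were seen, stood at 10.82 in sample 3 and at 6.65, 6.49 and 6.29, below background, in samples 1, 2 and 4. CD38 stood at 9.61 in sample 3 and 8.57, 7.76 and 7.65 in samples 1, 2 and 4. B cell genes deviated by +0.26, +0.59, −0.37 and −0.49 in samples 1 to 4 (adjusted p = 0.000525, permutation test), neutrophil genes by −0.67, −0.37, +0.43 and +0.61 in samples 1 to 4 (0.000525), dendritic cell genes by +0.82 in sample 4 (0.00452) and erythroid genes by +0.61 in sample 4 (0.00153). Platelet genes did not pass (adjusted p = 0.330, permutation test). Basophil genes did not pass either (adjusted p = 0.0661, permutation test). Each of these lists had at most 3 members above background on every array. With values below the limit set to it, the sample 4 values shrank to −0.07 ± 0.04 for B cell, +0.10 ± 0.07 for neutrophil, +0.50 ± 0.23 for dendritic cell and +0.36 ± 0.12 for erythroid genes (SE over genes), the B cell and neutrophil values within 2 standard errors of 0.

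Several genes of the interferon gamma response were highest in sample 1. The guanylate-binding protein genes GBP4 and GBP5 stood at 10.71 and 11.61 in sample 1 and at 8.81 and 10.35 in sample 4, and CXCL9 at 9.64 in sample 1. The 13 genes of an interferon gamma list above background had a shift SD of 0.720 (p = 0.0001, the smallest the permutation test can give). Because the list was written after CXCL10 and IDO1 were seen to vary, this cannot show that an interferon gamma response may be the source. Without the 4 members among the 25 most variable genes, the shift SD of the other 9 was 0.49 (p = 0.0001, permutation test). Those 9 come from the same list written after the variable genes were seen, so this does not remove that choice.

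Endoplasmic reticulum stress genes were 0.51 ± 0.13 log2 units (SE over 15 genes) higher in sample 3 than in the mean of the others. Of them, 8 above background had a shift SD of 0.44 (adjusted p = 0.0005, permutation test over 2 lists). This list too was written after the variable genes were seen, so these values cannot show that such a stress response was the source.

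GPNMB and SPP1 mark maturing macrophages, and SPP1 stood at 9.55 and 8.68 in samples 1 and 2 but below background in samples 3 and 4. GPNMB stood at 11.12, 11.35, 8.68 and 11.51 in samples 1 to 4, so these genes parted in sample 4. Maturation of monocytes into macrophages could raise both, but 16.7% of the macrophage list was above background against 38.5% of other genes (p = 0.0340, adjusted over 6 lists 0.102, Fisher's exact test). This did not decide, since a gene raised in some samples only does not count as above background on all 4 arrays. On single arrays, 7, 11, 9 and 7 of the 24 genes exceeded the limit in samples 1 to 4.

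Genes for which 3 samples lay within 0.3 log2 units and the other differed by 0.8 or more were counted. Samples 1 to 4 were the higher one for 7, 5, 23 and 22 genes and the lower one for 1, 26, 12 and 31 genes.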
